A study of Homo sapiens with 6 samples.

How the data were processed

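Total RNA of 6 RD18 cultures was hybridised to 1 array each. The growth and treatment notes describe 6 days of doxycycline at 1 µg/ml for induced cells and no treatment for the others. The table used here holds 1 column per array and 33297 rows, each a set of probes for 1 transcript. Its values are log2 expression made by the authors with RMA in Partek, per the submitters' processing notes, which give no versions or parameters. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of a transcript, so the deposited values of different arrays share nearly the same distribution and a change of all transcripts together would not be seen. The deposited log2 values ran from 1.1 to 14.09, with no centring per gene. The chip type is named in the labels of 2 arrays. The genome build and the chip's library file are not given in the sources used here. The arrays carry no detection calls in the table, and raw scanner files were not used here, so signal over background is known only through the log2 level.

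Groups were taken from the sample titles: induced and non-induced miR-22 cells with 2 arrays each, and induced and non-induced NpBI-206AS cells with 1 array each. The series describes the miR-22 replicates as biological. Rows were named through the platform's gene annotation, with symbols updated by gene ID through the NCBI gene table of assembly GRCh38.p14; of 19460 rows with a single symbol, 19429 had their gene ID in that table. A further 1754 rows carried several symbols and 12083 none, and no gene was named from those. The single-symbol rows covered 18417 genes, of which 769 had more than 1 row; a gene was represented by its row with the highest mean over all 6 arrays. On 4 rows the values were identical on all 4 miR-22 arrays.

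All tests used limma 3.58.1 in R 4.3.3 on the deposited log2 values, two-sided, with Benjamini-Hochberg adjustment over all 33297 rows and a threshold of 0.05. Designs, gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The main comparison, induced against non-induced miR-22 cells, and the difference between that response and the response of NpBI-206AS cells came from 1 linear model with a mean per group over all 6 arrays, followed by moderation of the variances with eBayes (2 residual degrees of freedom, 3.62 prior degrees of freedom). A second model set the 2 induced miR-22 arrays against the other 4. No replicate block was used in the main design, because the labels only number the replicates. The array code prefix could not be a covariate, since every induced miR-22 array has a prefix that no other array shares. With 1 array per condition, NpBI-206AS cells were described by differences only: the number of genes at least 2-fold apart, and each list's median with its percentile among 10000 random lists of equal size matched on mean expression. These percentiles describe the 2 arrays and are not tests.

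A set of 29 gene lists covered muscle differentiation, muscle progenitors, cell cycle, miR-22 targets from the literature, the 3 targets tied to this study, signalling, stress, metabolism, matrix, short noncoding RNAs and markers of other cell types. The lists of short noncoding RNAs, histones and microRNA genes were filled by symbol pattern. The list of mitochondrially encoded genes had no measured member, which left 28. Lists were tested with camera at a preset correlation between genes of 0.01, with the correlation estimated instead, and with fry, and adjusted over the lists. Camera asks whether a list's genes move relative to the other genes; fry asks whether they move on balance in 1 direction, and its mixed version whether they move in either direction. Members were also counted after adjustment over the list alone.

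Named genes followed a fixed rule. For the main comparison these were the 12 genes with the largest rise and the 12 with the largest fall among genes that passed and whose induced arrays both lay on the same side of both non-induced arrays. For the comparison with all controls and for the difference between the lines' responses they were the 5 largest each way by the same rule, or by log2 change among rows with an unadjusted p under 0.05 where too few passed. For NpBI-206AS cells they were the 5 largest each way of at least 2-fold. MIR22HG, MIR206, TACC1, RAB5B and ERBB3 were always read. From each list, up to 4 members that passed were named, and otherwise up to 2 with the largest difference.

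The models were tested on simulated arrays with the real rows and known changes. The main comparison recovered 1.49% of rows shifted by 1 on the log2 scale, 83.6% of those shifted by 2 and 98.5% of those shifted by 3. The comparison with all 4 control arrays recovered 50.7%, 95.5% and 100%, and the difference between the responses of the 2 lines 0% at each size. Only 66 or 67 of 33297 rows were changed at each size. With so few changed rows the adjustment asks for smaller p than in the real data. These rates therefore do not carry over to the real comparisons. A simulated list of 40 genes shifted by 1 had a camera adjusted p of 3.3e-56 with the preset correlation. With an estimated correlation it was 0.106, so the estimated version did not reach the threshold even for such a list in this design. The simulated genes varied independently of each other, so this run cannot show whether the preset correlation holds for the real lists.

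Alternatives covered the variance model, array weights, the arrays in the fit, the replicate number as a block, the prefix as a random block, a repeated quantile normalization, cyclic loess, centring on array medians, removal of the dimmest 25 and 50 percent of rows, the rows tested, the mean of all rows of a gene, a 2-fold threshold, the set test and leaving out each array in turn. Enrichment of miR-22 sites in 3' untranslated regions, planned in case transcript sequence was at hand, was not analysed here.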

Results

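Gene expression was measured on 6 Affymetrix Human Gene ST arrays, which read each transcript with many short probes along its length. The RNA came from RD18 cells, an established line of embryonal rhabdomyosarcoma, a soft-tissue tumour with features of immature skeletal muscle. In the RD18 derivative named NpBI-22 (miR-22 cells below), doxycycline switches on miR-22, a microRNA that lowers the mRNAs it pairs with. The miR-22 cells were profiled as 2 biological replicates after 6 days of doxycycline at 1 µg/ml (induced) and as 2 replicates without it (non-induced). A second derivative, NpBI-206AS, served as an additional control with 1 induced and 1 non-induced array; the labels do not say what the suffix stands for or what the construct expresses once induced. A difference between its 2 arrays thus holds doxycycline and any product of the construct together. Array medians lay between 5.66 and 5.75 on the log2 scale. The number of arrays, rather than any depth, limits the precision of every value below.

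The labels also give each array a code. Both induced miR-22 arrays carried the code prefix R715, which none of the other 4 arrays had; non-induced replicate 1 carried R509, and non-induced replicate 2 and both NpBI-206AS arrays carried R587. The labels do not say what the prefix means. If it marks a batch, batch and induction cannot be told apart in any comparison that involves the induced miR-22 arrays. Across all rows, the 2 induced arrays correlated at r = 0.9927 and differed 2-fold or more in 18 genes. The 2 non-induced miR-22 arrays, with different prefixes, correlated at r = 0.9866 and differed that much in 111 genes. Non-induced replicate 2 and non-induced NpBI-206AS cells, which share a prefix, correlated at r = 0.9945 and differed in 56 genes. Replicate 2 and induced NpBI-206AS cells differed in 58. Non-induced replicate 1, of another prefix, differed from non-induced and induced NpBI-206AS cells in 327 and 240 genes. Every pair with a shared prefix correlated at r = 0.9927 or more, and every other pair at 0.9866 or less. Similarity between arrays thus followed the prefix, also across the 2 lines. Between induced and non-induced miR-22 arrays r lay between 0.9748 and 0.9794, with 739 to 1175 genes apart.

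The main comparison asked which transcripts differ once miR-22 is induced. As a check of the labels, the host gene of miR-22, MIR22HG (row 8011193), was read first. Its log2 expression was 10.02 ± 0.0062 (SD, n = 2) in induced and 6.49 ± 0.32 (SD, n = 2) in non-induced miR-22 cells, and 6.41 and 6.32 in non-induced and induced NpBI-206AS cells. It was thus 11.5-fold higher in induced miR-22 cells (log2 change 3.53, SE 0.197, limma adjusted p = 0.014). Probe and construct sequences were not used here. Signal from a transcript of the construct therefore cannot be told apart from that of the host gene itself, here and wherever MIR22HG is named below. No row carried the microRNA gene itself as its single symbol, so the mature microRNA was not measured here. TACC1, RAB5B and ERBB3, genes tied to this study by its publication, were all lower. TACC1 (row 8145954), which encodes a protein of the centrosome and spindle, fell by 1.63 on the log2 scale (SE 0.146, adjusted p = 0.018). It read 7.96 ± 0.018 in induced and 9.58 ± 0.053 in non-induced cells (SD, n = 2), and 9.62 and 9.59 in non-induced and induced NpBI-206AS cells. RAB5B (row 7956088), a GTPase of early endosomes, fell by 1.19 (SE 0.161, adjusted p = 0.028). ERBB3 (row 7956120), a receptor of the epidermal growth factor receptor family, fell by 1.41 (SE 0.145, adjusted p = 0.02).

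**Figure D1:**
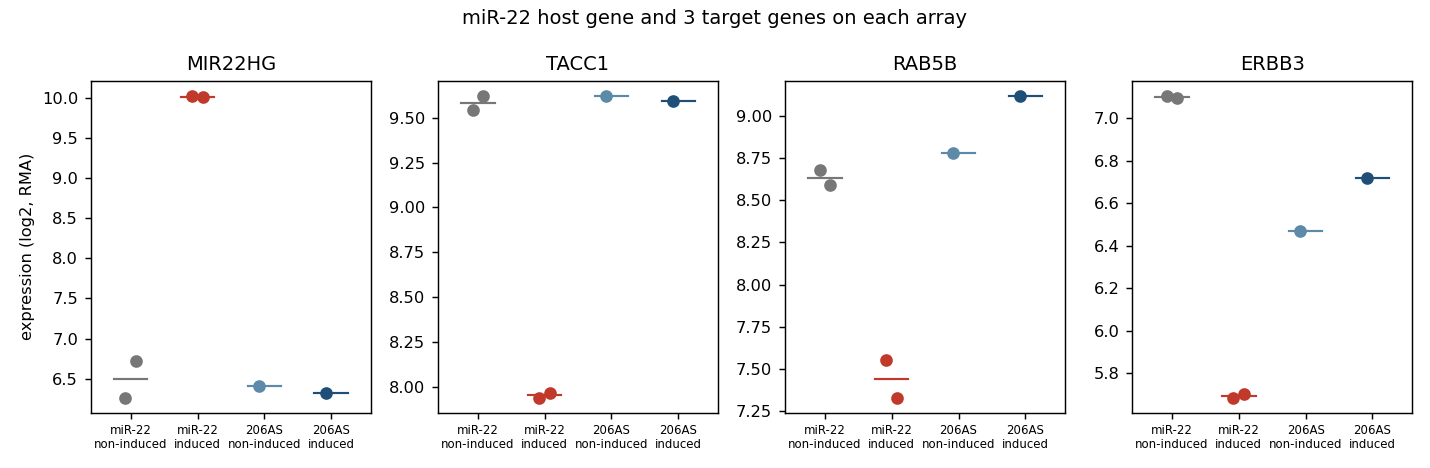
Log2 expression (RMA) of MIR22HG, TACC1, RAB5B and ERBB3 on each of the 6 arrays; each point is 1 array, each line the mean of its group, and the vertical axis of each panel spans its own range and does not start at 0. MIR22HG lay near 10.02 on both induced miR-22 arrays and between 6 and 7 on the other 4, while the 3 target genes were lowest on the induced miR-22 arrays.

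These 3 genes may have been chosen by the study on these same arrays, so their direction is not independent evidence. ERBB3 also differed between control cultures: it read 7.1 in non-induced miR-22 cells against 6.47 and 6.72 in non-induced and induced NpBI-206AS cells. MIR206, the row of a microRNA gene of skeletal muscle, fell by 1.52 (SE 0.193, adjusted p = 0.026).

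Across the array, 531 of 33297 rows were higher and 669 lower in induced than in non-induced miR-22 cells at an adjusted p under 0.05, and 991 of these 1200 rows differed at least 2-fold. In terms of genes with a row of their own symbol, 319 were higher and 281 lower among 18417. The largest rise was that of KLHL13, an adaptor of the CUL3 ubiquitin ligase, from 3.90 ± 0.11 to 7.72 ± 0.18 (SD, n = 2 per group), a log2 change of 3.82 (SE 0.17, adjusted p = 0.014). Its lower level lay under the lower quartile of the non-induced arrays (4.01 and 3.98) and is not shown to be above background. The lower levels of RNU4-2, POSTN, MYH8, MIR148B and MIR221 below also lay under the lower quartiles; if these levels are background, the differences given for these genes between induced and non-induced miR-22 cells are minima and their ranks are not exact. ARHGAP29 rose by 3.53, and KITLG, the ligand of the KIT receptor, by 3.13. The sialyltransferase genes ST6GALNAC3 and ST6GALNAC5 rose by 2.80 and 2.40, the sulfotransferase gene UST by 2.55 and KLHL4, of the same kelch family as KLHL13, by 2.53. The remaining 4 of the 12 largest rises were short noncoding RNAs, described with their list below. Of the 12 largest falls, 5 were muscle genes: MYH3 (-2.79), TNNC1 (-2.35), CAVIN4 (-2.19), MYBPH (-2.12) and MYH8 (-2.08). A further 3 belong to cell division: the kinetochore motor CENPE (-2.42), the proliferation marker MKI67 (-2.05) and SPC24 of the kinetochore (-2.02). The others were the germ-cell gene TEX15 (-2.66), NT5E, an enzyme that makes adenosine at the cell surface (-2.52), the pseudogene ADCY10P1 (-2.38) and CRYBG1 (-2.30). Adjusted p lay between 0.014 and 0.032 for all 24.

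With any 1 of the 4 miR-22 arrays left out, 0 rows passed in limma, with 3526 to 8113 rows at an unadjusted p under 0.05 and, with all arrays, 7189. Centring each array on its median turned the split of 531 higher and 669 lower rows into 718 higher and 574 lower.

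Of 28 gene lists fixed beforehand that had measured members, 16 passed limma's camera test with its preset correlation, 10 upward and 6 downward. None passed when the correlation between genes was estimated from the arrays, and neither did a simulated list of 40 genes shifted by 1. Among lists that passed, the estimate was 0.4 for histones, 0.39 for DNA replication, 0.067 for muscle genes and -0.03 for literature miR-22 targets. Where genes of a list correlate above the preset 0.01, the preset adjusted p is too small. The estimates rest on 2 residual degrees of freedom. In the self-contained test fry, 7 lists moved on balance in 1 direction, 3 upward and 4 downward. Of these, the 3 targets tied to the study had a fry adjusted p of 0.0096 and the literature targets 0.013. The literature list holds those 3 genes. Without them, in a test chosen after seeing the data, its fry adjusted p was 0.049. The muscle, mitosis, RAS/ERK, small nuclear RNA and neural lists had 0.049 each. Histones, cholesterol synthesis, ribosomal proteins, NF-kB, p53 and apoptosis did not pass (fry adjusted p = 0.094 each). Nor did ATF4 targets (0.12), DNA replication (0.25) or the respiratory chain (0.28). In fry's mixed version every list passed except the respiratory chain (adjusted p = 0.057) and epithelial markers (0.52). Blood (0.028) and endothelial markers (0.014) passed it too, so it set few lists apart.

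Muscle differentiation and contraction genes were lower as a group: 17 of 43 fell, none rose, and the list's median log2 change was -1.0 (camera adjusted p = 4.1e-18; adjusted p = 0.35 with an estimated correlation). Adjusted over the list alone, 28 fell and 1 rose. MYH3, the embryonic myosin heavy chain, went from 7.85 ± 0.23 to 5.06 ± 0.28 (SD, n = 2), and MYH8, the perinatal one, from 5.66 ± 0.31 to 3.58 ± 0.0061. TNNC1, a troponin of slow and cardiac muscle, and the myosin-binding protein gene MYBPH fell 5.09-fold and 4.35-fold. The same list was also lower in untreated NpBI-206AS than in untreated miR-22 cells, with a median of -0.81 for non-induced NpBI-206AS cells minus non-induced miR-22 replicate 2 (1 array each, both of prefix R587). Against the 3 control arrays of prefix R587 together, the induced miR-22 arrays had a list median of -0.40. Relative to non-induced and induced NpBI-206AS cells alone, their list medians were -0.229 and -0.126. Among 28 regulators of muscle progenitors, limma called 0, over all rows or over the list alone, with 5 higher and 3 lower at an unadjusted p under 0.05 (median 0.06, camera adjusted p = 0.81); HES1 and MSTN had the largest differences, 1.22 (adjusted p = 0.064) and 1.2 (adjusted p = 0.099).

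Genes of mitosis and the G2/M phases were also lower, with 7 of 39 falling, none rising and a median of -0.61 (camera adjusted p = 8.4e-16; adjusted p = 0.35 with an estimated correlation). Adjusted over the list alone, 24 fell. Besides CENPE and MKI67, CENPF fell by 1.54 and NUF2 by 1.54, both of them kinetochore genes. Of DNA replication and S phase genes, 3 of 39 fell (4 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 8.7e-05; adjusted p = 0.56 with an estimated correlation). The median was -0.47 without induced replicate 1 and -0.12 without induced replicate 2. The fallen genes were the checkpoint adaptor CLSPN (-1.48), CDC45 of the replicative helicase (-1.08) and the primase subunit PRIM1 (-1.07). In NpBI-206AS cells, the single induced array lay below the single non-induced array in both lists, by medians of -0.27 and -0.39. Subtracting that response left the mitosis median at -0.36 but turned the DNA replication median to 0.0321 (camera adjusted p = 0.66). It left -0.46 for CDC45 (SE 0.306) and -0.41 for PRIM1 (SE 0.276), while CLSPN kept -0.91 (SE 0.263).

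Of 31 miR-22 targets named in the literature, 6 fell and none rose, with a median of -0.20 (camera adjusted p = 3e-04; adjusted p = 0.35 with an estimated correlation); adjusted over the list alone, 9 fell and 1 rose. The median ran from -0.127 with the rows of a gene averaged to -0.33 without non-induced replicate 1 or the dimmest 50 percent of rows. The list holds TACC1, ERBB3 and RAB5B, and beside them NCOA1, a coactivator of nuclear receptors, fell from 9.19 ± 0.028 to 7.75 ± 0.17 (SD, n = 2). Without those 3 genes, a test chosen after seeing the data, 3 of 28 fell (5 adjusted over the list alone) and none rose, with a median of -0.12 (camera adjusted p = 0.013; adjusted p = 0.42 with an estimated correlation). The list of those 3 genes alone had a median of -1.40 (camera adjusted p = 2.4e-05; adjusted p = 0.35 with an estimated correlation), and adjusted over the list alone 3 of 3 fell, which is not independent evidence. Among 189 rows named for microRNA genes, 1 rose and 3 fell, also adjusted over the list alone, and the list did not pass (median -0.03, or 0.04 with each array centred on its median; camera adjusted p = 0.18). The rise was MIR22HG and the falls were MIR206, MIR148B (-1.5) and MIR221 (-1.45).

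Small nuclear and other short noncoding RNAs had a median of 0.98: 12 of 31 rose and 1 fell (camera adjusted p = 9.2e-09; adjusted p = 0.42 with an estimated correlation). The median was 0.58 without non-induced replicate 2 and 1.52 without the dimmest 50 percent of rows. Adjusted over the list alone, 16 rose and 1 fell. The spliceosomal RNA genes RNU4-2, RNU5E-1 and RNU5D-1 rose by 2.84, 2.60 and 2.45, and RPPH1, the RNA of ribonuclease P, by 2.54, from 8.08 ± 0.5 to 10.61 ± 0.16 (SD, n = 2). Replication-dependent histone genes rose with 12 of 60 members and a median of 0.70 (camera adjusted p = 2.6e-15; adjusted p = 0.42 with an estimated correlation); adjusted over the list alone, 32 rose and 1 fell. H4C4 rose by 1.98, H2AC1 by 1.5, H2BC3 by 1.44 and H2AC16 by 1.35. Among 192 small nucleolar and Cajal body RNAs, 8 rose and 7 fell (22 and 16 adjusted over the list alone), with a median of -0.03, or 0.04 with each array centred on its median (camera adjusted p = 0.36). SCARNA10, SNORD13P3 and SNORD13 rose by 2.28, 2.21 and 2.04, while SNORD52 fell by 1.43. Probe sequences were not used here, so signal shared among near-identical histone or spliceosomal RNA genes was not assessed.

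ATF4 targets of the integrated stress response rose in 4 of 36 members (13 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 2.4e-05; adjusted p = 0.42 with an estimated correlation). These were CHAC1 (1.40), which degrades glutathione, the amino acid transporter subunit SLC3A2 (1.23), asparagine synthetase ASNS (1.17) and the tryptophan tRNA ligase WARS1 (0.85). Cholesterol synthesis genes rose in 3 of 23 members (10 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 2.7e-05; adjusted p = 0.42 with an estimated correlation). The enzymes MVK, DHCR7 and SQLE rose by 1.46, 1.40 and 1.02, and in NpBI-206AS cells the induced array was above the non-induced array by a list median of 0.54. Subtracting that response turned the list's median to -0.211 (camera adjusted p = 0.46). Cytoplasmic ribosomal proteins had 2 risen members of 41, also adjusted over the list alone, RPL32 (0.88) and RPS19 (0.88), and a median of 0.33 (camera adjusted p = 3.6e-06; adjusted p = 0.42 with an estimated correlation). Of 30 nuclear-encoded respiratory chain genes limma called 0 (4 higher adjusted over the list alone, 8 at an unadjusted p under 0.05), although the list did, with a median of 0.23 (camera adjusted p = 0.0023; adjusted p = 0.56 with an estimated correlation). COX6A1 and NDUFB3 differed by 1.38 and 1.29 (adjusted p = 0.15 and 0.067). In these 4 lists non-induced replicate 1 lay below replicate 2, by medians of -0.24 for ATF4 targets, -0.19 for cholesterol synthesis, -0.19 for ribosomal proteins and -0.29 for the respiratory chain. Without replicate 1, the respiratory chain list did not pass (median 0.17, camera adjusted p = 0.099), and without replicate 2 its median was 0.39.

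**Figure D2:**
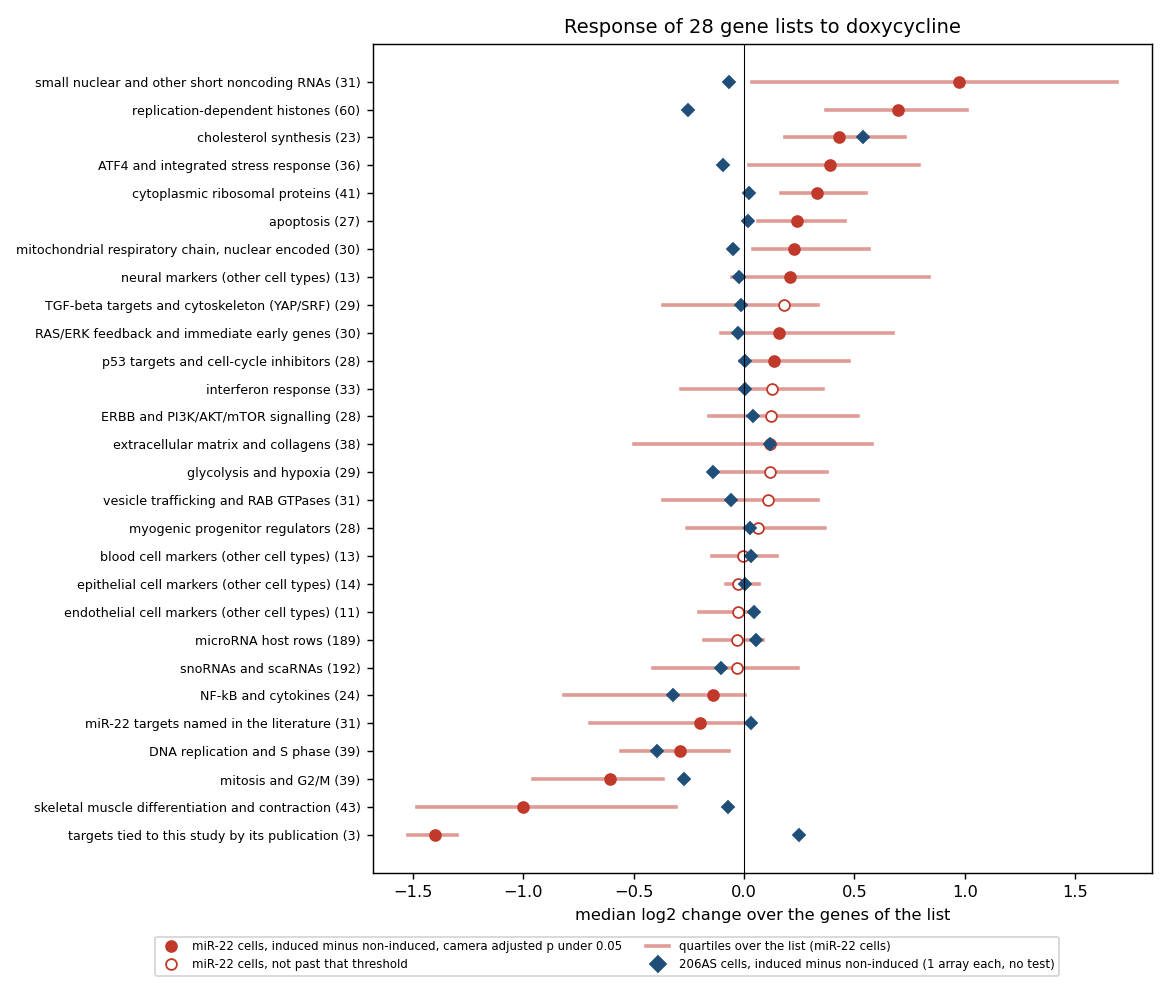
Median log2 change of 28 gene lists (number of measured genes in brackets); red points are induced minus non-induced miR-22 cells (2 arrays each; filled where the camera adjusted p with preset correlation was under 0.05), red bars the quartiles over the genes of a list, and blue diamonds induced minus non-induced NpBI-206AS cells (1 array each, no test). Small nuclear RNAs (0.98) and histones (0.70) stood at the top, and muscle genes (-1.0) and the 3 targets tied to the study (-1.40) at the bottom; cholesterol synthesis was above 0 in both lines.

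Immediate early and RAS/ERK feedback genes rose in 3 of 30 members (7 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.029; adjusted p = 0.42 with an estimated correlation). HBEGF, a ligand of the epidermal growth factor receptor, rose by 1.60, IER2 by 0.99 and the transcription factor gene FOS by 0.97. Among p53 targets and cell-cycle inhibitors 1 of 28 rose (3 adjusted over the list alone), the apoptosis inhibitor TRIAP1 by 1.00, with a median of 0.14 (camera adjusted p = 0.046; adjusted p = 0.42 with an estimated correlation). After quantile normalization was applied again, these lists had camera adjusted p of 0.056 and 0.082, and without the dimmest 50 percent of rows 0.051 and 0.074. The p53 list also did not pass with the replicate block (0.051), cyclic loess (0.074) or each array centred on its median (0.054). Leaving out 1 array also ended their calls: without induced replicate 1 or non-induced replicate 2 the RAS/ERK list had camera adjusted p of 0.082 and 0.058, and without induced replicate 2 or non-induced replicate 1 the p53 list had 0.09 and 0.22. The RAS/ERK median was 0.28 without non-induced replicate 2. The apoptosis list passed with a median of 0.24 (camera adjusted p = 0.018; adjusted p = 0.42 with an estimated correlation), and a median of 0.38 without the dimmest 50 percent of rows, but limma called 0 of its 27 genes, over all rows or over the list alone, with 6 higher and 1 lower at an unadjusted p under 0.05. BAK1 and DIABLO differed by 1.26 and 0.85 (adjusted p = 0.053 and 0.18). NF-kB targets and cytokines fell in 2 of 24 members (7 adjusted over the list alone), the chemokine genes CXCL2 (-1.41) and CXCL1 (-0.91), with a median of -0.14 (camera adjusted p = 0.0029; adjusted p = 0.42 with an estimated correlation). Induced minus non-induced NpBI-206AS cells gave a median of -0.32 for this list, with CXCL2 at -1.60 and CXCL1 at -1.42, and subtracting that response turned the median to 0.0672. In miR-22 cells the median ran from -0.0694 with each array centred on its median to -0.465 without the dimmest 50 percent of rows, and was -0.24 without induced replicate 1 and -0.27 without non-induced replicate 2.

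The remaining lists of signalling and matrix genes did not pass as groups (camera adjusted p between 0.35 and 0.83), and some of their members moved in opposite directions. They did pass fry's mixed version, which counts movement in either direction (adjusted p between 0.001 and 0.0042). Their medians were not stable: over the alternative settings of this comparison and with 1 array left out they ran from 0.0841 to 0.254 for TGF-beta, -0.00516 to 0.188 for matrix, 0.00323 to 0.192 for ERBB and PI3K, 0.0473 to 0.189 for glycolysis, 0.0196 to 0.202 for interferon and -0.00754 to 0.181 for vesicle trafficking. Of 29 TGF-beta targets and cytoskeletal genes, 3 rose and 4 fell (4 and 5 adjusted over the list alone; median 0.18). TGFB2 (2.04), CCN2 (1.42) and the smooth muscle calponin CNN1 (1.13) rose, and the matrix protein gene TGFBI fell by 1.68. Of 38 extracellular matrix genes, 3 rose and 3 fell (9 and 8 adjusted over the list alone; median 0.12); POSTN rose by 1.84, TIMP3 by 1.32 and THBS1 by 1.02, while LOX, a collagen crosslinking enzyme, fell by 1.11. Of 28 genes of ERBB and PI3K signalling, 2 rose and 1 fell (3 and 2 adjusted over the list alone; median 0.12). The PI3K subunit genes PIK3CB and PIK3R3 rose by 1.23 and 1.1, and ERBB3 fell. Glycolysis and hypoxia genes had 2 falls among 29, also adjusted over the list alone, LOX and the phosphofructokinase gene PFKP (-0.99), with a median of 0.12. Of 33 interferon response genes the peptide transporter gene TAP1 alone fell, by 1.23, also adjusted over the list alone (median 0.13). Of 31 genes of vesicle trafficking RAB5B alone fell, also adjusted over the list alone; here the median was 0.11, the mean -0.04 and the direction of the test downward.

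Markers of other cell types gave 0 calls in limma for epithelial (14 genes), blood (13) and endothelial cells (11), over all rows and over each list alone. At an unadjusted p under 0.05 there were 0 epithelial genes, 1 higher and 1 lower blood gene and 1 lower endothelial gene, with medians of -0.03, -0.01 and -0.03 (camera adjusted p = 0.83, 0.81 and 0.52), and all 3 medians were above 0 with each array centred on its median. The epithelial list had a mean of 0.004 with a median and test in the other direction. Its largest differences were KRT18 (0.40, adjusted p = 0.3) and CLDN4 (-0.21, adjusted p = 0.49). For blood they were CD68 (-0.73, adjusted p = 0.08) and HBB (0.51, adjusted p = 0.12), and for endothelium PECAM1 (-0.53, adjusted p = 0.12) and EMCN (0.36, adjusted p = 0.28), with EMCN under the lower quartile in every group. Of 13 neural markers 2 rose (3 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.031; adjusted p = 0.42 with an estimated correlation). INA, a neuronal intermediate filament, rose from 6.51 ± 0.22 to 8.72 ± 0.11 (SD, n = 2), and SYT1, a synaptic vesicle protein, from 5.24 ± 0.46 to 7.04 ± 0.23. Without induced replicate 2 or non-induced replicate 2, the neural list did not pass (camera adjusted p = 0.065 and 0.1), and without the dimmest 50 percent of rows, which left 6 genes, its median was 0.87.

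A second comparison set the 2 induced miR-22 arrays against all 4 arrays without induced miR-22, so that the spread includes differences between the control lines. KLHL13 was higher by 3.84 on the log2 scale (SE 0.125, adjusted p = 0.00011), MIR22HG 12-fold (3.59, SE 0.149, adjusted p = 0.00016), ARHGAP29 8.72-fold and KITLG 7.28-fold. The other gene among the 5 largest rises was MINAR2 (2.78, adjusted p = 0.0065), which, like KLHL13, lay under the lower quartile in the controls on average, so both differences are minima if that is background. NT5E (-2.82), CRYBG1 (-2.73), CENPE (-2.65), TEX15 (-2.63) and ADCY10P1 (-2.45) were the lowest, with adjusted p between 0.00071 and 0.005. Without induced replicate 1, MINAR2 and CRYBG1 did not pass (adjusted p = 0.081 and 0.067). TACC1 was lower by 1.64 (adjusted p = 0.00047), RAB5B by 1.35 (adjusted p = 0.0034) and ERBB3 by 1.15 (adjusted p = 0.0099). MYH3, which was already lower in NpBI-206AS cells, did not pass (-1.95, SE 0.559, adjusted p = 0.059). Nor did the muscle genes MYBPH (adjusted p = 0.11) and MYH8 (0.14), the chemokine genes CXCL2 (0.052) and CXCL1 (0.13), or MVK (0.079) and DHCR7 (0.069) of cholesterol synthesis. The muscle genes TNNC1 (-1.78, adjusted p = 0.028), CAVIN4 (-1.81, 0.0071) and NEB (-1.83, 0.0095) did pass, as did SQLE of cholesterol synthesis (0.92, 0.019). In all, 2103 rows were higher and 2473 lower; as genes, 1432 were higher and 1163 lower. Centring each array on its median gave 2628 higher and 2042 lower. The total of 4576 rows changed to between 897 (without induced replicate 1) and 7463 (without non-induced replicate 1) when 1 array was left out. It was 1492 without induced replicate 2, 2641 without non-induced replicate 2, and 2935 and 3020 without the non-induced and the induced NpBI-206AS array. With the prefix as a random block, 1628 rows passed.

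The third comparison subtracted the response of NpBI-206AS cells to doxycycline from that of miR-22 cells, which leaves out what doxycycline does in both lines but brings in, with the opposite sign, anything the NpBI-206AS construct does once induced. The 5 highest differences between responses were those of KLHL13 (3.98, SE 0.294), MIR22HG (3.62, SE 0.342), KITLG (3.40, SE 0.301), RNU4-2 (3.34, SE 0.459) and ARHGAP29 (2.93, SE 0.368). KLHL13 lay under the lower quartile in all 3 control groups, and RNU4-2 in non-induced miR-22 and induced NpBI-206AS cells, so their differences and ranks here are not exact. The 5 lowest were those of ADCY10P1 (-2.95, SE 0.315), the giant thin-filament protein gene NEB (-2.55, SE 0.613), CENPE (-2.37, SE 0.507), MYH3 (-2.35, SE 0.366) and LOC285097 (-2.26, SE 0.36). None of these passed after adjustment (adjusted p from 0.18 to 0.38), and the differences for TACC1 (-1.60), RAB5B (-1.53) and ERBB3 (-1.65) had adjusted p of 0.27, 0.3 and 0.27. Over all rows limma called 0, with 2957 rows at an unadjusted p under 0.05, and an ordinary fit without variance moderation, added after the data were seen, called 9. The NpBI-206AS arrays, 1 per group, were assumed to vary like the miR-22 arrays, and the standard error was typically 1.73 times that of the main comparison. On simulated data this contrast recovered 0% of rows shifted by 3 on the log2 scale. Few rows were changed in that simulation, so the rate does not show what this contrast could detect in the real data.

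Induced and non-induced NpBI-206AS cells were compared on 1 array each, with no replicate check and no test. INSIG1, a regulator of sterol synthesis, was higher in induced cells by 1.22 on the log2 scale, along with MACC1 (1.31), LOC285097 (1.18), MOXD1 (1.15) and the galectin gene LGALS9 (1.1), which lay under the lower quartile on both arrays (2.451 and 3.556) and is not shown to be above background. The protease inhibitor gene TFPI2 was lower (-2.27), as were the interleukin receptor gene IL7R (-1.76) and the chemokine genes CXCL2 (-1.60), CCL20 (-1.49) and CXCL1 (-1.42). In total 8 genes were higher and 12 lower by at least 2-fold. The cholesterol synthesis list had a median of 0.54, above all 10000 random lists of equal size matched on mean expression (percentile 100). DNA replication (-0.39), NF-kB targets and cytokines (-0.32), mitosis (-0.27), histones (-0.25) and small nucleolar and Cajal body RNAs (-0.105) lay below all of them (percentile 0). Glycolysis (-0.14), small nuclear RNAs (-0.07) and muscle genes (-0.07) lay at percentiles 0.29, 0.98 and 1.07, and the 3 targets tied to the study (0.25), ribosomal proteins (0.02) and matrix genes (0.12) at 98.75, 99.95 and 99.99. MIR22HG differed by -0.09 and TACC1 by -0.03 between the NpBI-206AS arrays. Across 18417 genes, which are not independent replicates, the response of miR-22 cells and the difference in NpBI-206AS cells correlated at r = 0.0731, and over the called genes alone at r = 0.281. Genes higher in induced miR-22 cells had a median of 0.02 in NpBI-206AS cells, and genes lower in them a median of -0.11, against medians of 1.23 and -1.17 in miR-22 cells. Of the 600 genes called in miR-22 cells, 7 differed 2-fold or more between the NpBI-206AS arrays, against 20 of all 18417 genes. The share was thus larger among the called genes than among all genes.

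**Figure D3:**
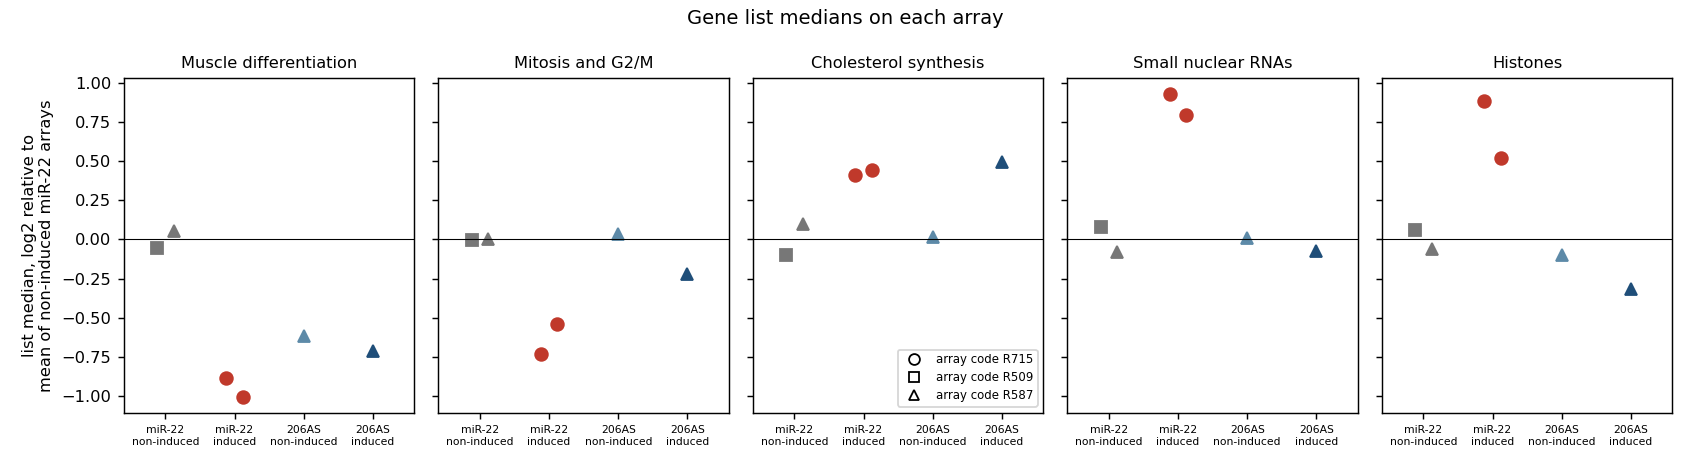
Median of 5 gene lists on each array, as log2 expression relative to the mean of the 2 non-induced miR-22 arrays; each point is 1 array, and its shape gives the array code prefix. The muscle list lay at -0.89 and -1.01 on the induced miR-22 arrays and at -0.62 and -0.71 on the NpBI-206AS arrays, whereas small nuclear RNAs were high on the induced miR-22 arrays (0.93 and 0.80) and near 0 on the other 4.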

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

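The comparison of the 2 lines' responses was planned; the tests that weigh explanations in the last 2 paragraphs were chosen after the results were seen.

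In the difference between the responses of miR-22 and NpBI-206AS cells to doxycycline, 12 of the 28 gene lists passed camera with its preset correlation. With an estimated correlation 0 passed, and limma called 0 rows. It also called 0 on simulated data, where few rows were changed. The NpBI-206AS side is 1 array per condition and was assumed to vary like the miR-22 arrays, so a difference between the lines is not established by these tests. The median difference between responses was -0.77 for muscle genes (adjusted p = 1.8e-17), -0.36 for mitosis genes (2.4e-06), -0.31 for miR-22 targets from the literature (5.2e-05), -1.60 for the 3 targets tied to the study (1.2e-06) and -0.11 for microRNA gene rows (0.019). It was 0.28 for RAS/ERK and immediate early genes (adjusted p = 0.01), 0.50 for ATF4 targets (9.1e-07), 0.34 for the respiratory chain (0.002), 0.33 for ribosomal proteins (0.00014), 0.96 for histones (3.9e-21), 1.01 for small nuclear RNAs (5.1e-11) and 0.22 for neural markers (0.0081). In 11 of the 12 lists, all but the microRNA gene rows, both induced miR-22 arrays lay on the same side of both non-induced ones by list median. The 12 lists were picked for passing in a contrast that includes the difference between these same arrays, which favours such agreement. Among 14 genes checked over the 4 control arrays, no array stood apart from the other 3 by Dixon's ratio. Most of these genes were picked because they passed against those 4 arrays, which favours genes without such an array. The ratio also cannot flag a split of 2 arrays against 2.

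The fall of muscle genes in induced miR-22 cells (list median -1.0) was weighed against 3 explanations. Gene length is argued against: after removal of the trend on gene length the median was -1.02, below the lowest 2.5 percent of random lists (-0.121). Differences between cultures that have nothing to do with miR-22 could contribute, since non-induced NpBI-206AS cells lay below non-induced miR-22 replicate 2 by -0.81 with the same array prefix. The prefix itself cannot be told apart from induction, because no induced miR-22 array shares one with a control; the 2 non-induced arrays of different prefixes differed by -0.11 in this list. An effect of miR-22 on muscle differentiation remains open as a hypothesis, and so does a lower state of differentiation in these cultures for other reasons.

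Small nuclear RNAs (median 0.98) and histone genes (median 0.70) were higher in induced miR-22 cells, and below 0 in induced minus non-induced NpBI-206AS cells. More cells in S phase, which would raise histone mRNAs, is argued against as the whole cause because the DNA replication list did not rise: its median was -0.29 (upper quartile -0.0677), with -0.123 and -0.47 on the 2 induced arrays. Subtracting the NpBI-206AS response turned that median to 0.0321 (camera adjusted p = 0.66), against 0.96 for histones. Better recovery of all short RNAs is argued against by the small nucleolar RNA list, with a median of -0.0317 and an upper quartile of 0.244. The array prefix cannot be told apart from induction here either, and between the 2 non-induced arrays of different prefixes the small nuclear RNA list differed by 0.17.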

How the results depend on the processing

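The ordinary fits without moderation for the comparison with all controls and for the difference between responses, and the literature list without the 3 genes tied to the study, were chosen after seeing the data; the other alternatives were planned. For the 1200 rows of the main comparison, the ordinary fit gave 5. Removing the dimmest 25 and 50 percent of rows gave 1959 and 2609, testing only rows with 1 gene symbol 1999, and averaging the rows of a gene 1818. Fewer rows were then tested, and the variances were moderated over those rows alone. Every count without 1 of the miR-22 arrays was 0 (range 0 to 0). On simulated data, where few rows were changed, a fit without 1 non-induced array recovered 0% of rows shifted by 3. The counts without a non-induced array may thus say nothing about stability. A fit without 1 induced array recovered 86.4% of rows shifted by 3 but 2.99% of rows shifted by 2. Most called genes changed by less, and for them these counts say little about stability either. KLHL13 (3.82), ARHGAP29 (3.53), MIR22HG (3.53) and KITLG (3.13) rose by more than 3 with all arrays. Their calls in the main comparison were lost without either induced array, but also without either non-induced array. The loss therefore does not show that they rest on the induced arrays in particular. The replicate block gave 2955 rows; the replicate differences correlated at 0.196 over rows, with only 2 pairs, so the numbers are not taken to pair the samples. For the 4576 rows of the comparison with all controls, the ordinary fit gave 1780, the prefix as a random block 1628 (correlation 0.367), the 2-fold threshold 1398 and only the R587 controls 7463, with 897 to 7463 without 1 array. The difference between responses kept 0 rows except for 9 in the ordinary fit. The 224 rows that differed 2-fold or more in NpBI-206AS cells became 106 and 36 without the dimmest 25 and 50 percent, so dim rows near background made up much of that count. Of 16 gene lists, 0 passed with an estimated correlation and 7 in fry; the other settings gave 12 to 16. Under the contrast against NpBI-206AS cells, 6 of 28 list medians changed sign. The 3 among called lists were DNA replication (0.0321), cholesterol synthesis (-0.211) and NF-kB targets (0.0672). The cause of the changes in these counts and medians was not tested. For named genes in the main comparison, 1030 values under alternatives kept direction and side of the threshold, 370 lost the threshold, nearly all in the ordinary fit or with an array left out, 28 gained it and 0 changed sign. Of the list medians under alternatives, 376 kept their side of the threshold, though 21 of these, all in lists that did not pass, changed sign; 41 lost the threshold and 1 gained it. Normalization alternatives moved the median of all rows in the main comparison to at most 0.06. The prefix as a random block was not fitted for the main comparison, the difference between responses or the lists. Without a NpBI-206AS array the difference between responses cannot be formed, and the miR-22 site analyses were not run.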

Other observations

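All tests in this part were chosen after the result was seen.

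Among the list medians of untreated NpBI-206AS cells relative to non-induced miR-22 replicate 2, which share an array prefix, muscle genes stood lowest at -0.81. The next in size were neural markers (-0.19), cholesterol synthesis (-0.16) and small nuclear RNAs (0.13), with 1 array each and no test. For cholesterol synthesis, the induced miR-22 arrays stood at 0.50 above non-induced NpBI-206AS cells and at -0.02 relative to induced NpBI-206AS cells. For NF-kB targets and cytokines the same values were -0.23 and 0.06, and for DNA replication -0.33 and 0.02. These 3 lists were picked because they passed in the main comparison and their median changed sign in the difference between responses.

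Genes of chromosome 8 were higher as a group in induced miR-22 cells: the median log2 change of its 363 genes with a mean log2 above 6 was 0.17, the highest of 23 chromosomes, with 18 genes called higher and 7 lower. At most 0.01 percent of 10000 random sets matched on mean expression reached that median, the smallest share they can give, and the highest random median was 0.155. The chromosome was picked as the highest of 23, and the random sets treat genes as independent. This share therefore does not measure the chance of the result. A trend shared with the difference between the 2 non-induced arrays is argued against as the whole cause, since 0.113 was left after its removal. The upper bound for random sets, which have the same limits, was 0.0486. A block of neighbouring genes is a candidate explanation. Windows of 25 neighbours left out histone genes. Changes in them were centred on the median of all genes with a mean log2 above 6. The highest window median on the chromosome, from HAS2 to KHDRBS3, was 0.496, and 22 of the 25 genes were above 0 before centring. In 100 shuffled gene orders, treated alike, the highest window had a median of 0.368. Of these orders 0 reached 0.496, and the highest gave 0.493. Shuffled orders likewise treat neighbouring genes as independent, so they do not measure the chance of such a window. A change in copy number of that segment between the cultures may be a hypothesis, and DNA was not analysed here. The array prefix stays open as well.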
